A study of Mus musculus with 6 samples.

How the data were processed

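RNA from hepatocytes isolated from mice kept on a high-fat diet for 26 weeks was sequenced in 6 libraries, per the labels' protocols. The 3 XCON libraries came from Xbp1 floxed mice and the 3 XCKO libraries from mice with Xbp1 deleted in hepatocytes, all on a C57BL/6 background. Total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols. Whether counting used strand is not given in the sources used here, so the counts of overlapping and antisense genes are uncertain.

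The authors deposited 1 table with raw read counts per Ensembl gene for each library, and these counts were the unit of the main tests, as planned. The submitters' processing notes name Bowtie 0.12.2 and the builds mm8 and mm10 without giving their roles. The read counter is not given in the sources used here. Gene identifiers and coordinates in the table were compared with GENCODE M21 on GRCm38 (mm10). Of the identifiers, 99.8% were found there, 98.3% of these had the same start and end, and 100% overlapped on the same chromosome, so coordinates are given on mm10 as the table lists them. The authors' deposited FPKM values equalled the count divided by gene length and by a library size made of a median-of-ratios size factor and the geometric mean of the totals, with a ratio of 1 in all 6 libraries. The deposited group means are a signal on the scale of counts divided by size factors. The authors' deposited log2 fold changes, p-values and adjusted p-values come from a tool not given in the sources used here, and cover 24709 genes with at least 2 reads in all, of which 9133 have an adjusted p of 1. The deposited gene lengths were used for checks of length only. In 11 gene symbols a spreadsheet had left a date, and these were restored from the identifier. There were 103 repeated symbols. Symbols of 4 list genes were matched under another name, and 4 list genes were not in the table.

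Total counts were 23919355, 25160826 and 26502456 in XCON 1, 2 and 3 and 26999113, 26477489 and 27240079 in XCKO 1, 2 and 3. The table held 54532 genes, 27928 of them with no read in any library, and 14873 passed edgeR's filterByExpr at its defaults. Counts were scaled by TMM, with factors of 1.088, 1.086 and 1.117 in XCON and 0.916, 0.974 and 0.85 in XCKO. Genes were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust dispersion and robust quasi-likelihood fit) on group alone over all 6 libraries, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All adjusted p-values of single genes come from this test unless another is named. The biological coefficient of variation was 25.8%. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts scaled to the TMM-normalized library total, and errors of group means are SDs over 3 libraries. No mouse is named in the labels of single samples, although the series describes the groups as mice, so p-values measure the spread between these libraries.

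The 39 gene lists held 801 distinct genes, 769 of which were tested. Counts of list members below are of tested genes, which were 13 of 20 for the female-biased and 6 of 12 for the erythroid list. Each list was compared with all other tested genes by limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, two-sided, with Benjamini-Hochberg adjustment over the 39 lists. The correlation estimated from the data was the alternative. With it, camera's test also rests on the 4 residual degrees of freedom, rather than on the number of genes as with the preset correlation. Members past 0.05 were counted over all genes tested and adjusted over the list alone. Marker lists and lists of RNA state were also averaged per library and compared by a two-sided exact permutation test, whose 20 label assignments cannot give a p under 0.1.

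The design, the lists, the rule for naming genes and most of the other settings below were set before the data were examined. Xbp1 is named first, followed by 21 genes named whatever their values. Among genes past 0.05 with a mean of at least 5 CPM and groups that did not overlap, the 12 with the largest positive and the 12 with the largest negative log2 fold change are named, leaving out predicted genes with Gm or Rik names. For each list, up to 4 members with the smallest p among those past 0.05 are named, or the 1 member with the smallest p where none passed. Not every gene that this rule names is given.

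The tests were repeated with median-of-ratios size factors, no filter on low counts, a filter of 5 CPM in 3 samples, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with pseudocounts of 1 and 0.1 over genes with an FPKM of at least 1 in 3 samples, and the estimated correlation for the lists. Where fits without 1 library tied for the fewest list members called, only the first is named below, in the order XCON 1 to 3, then XCKO 1 to 3. Scaling by library totals alone and a correction for gene length were added after seeing the data. The length correction removed each library's smooth trend of log2 CPM on log2 gene length (loess span 0.5) as an offset in the same edgeR fit.

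Libraries were compared before averaging by a chi-square test of counts over genes with at least 10 reads. The chi-square per degree of freedom was 51.3 to 176.9 within groups, far from sampling noise, so each library counted as 1 replicate. The edgeR test was tested on simulated counts for 14553 genes of this comparison. It recovered 4% of genes changed 1.5-fold, 18.4% of those changed 2-fold, 63.3% of those changed 4-fold and 84% of those changed 8-fold. Of its calls, 6 (6.7%) were false. Only 49 or 50 genes were changed at each size, far fewer than the 1378 genes called in the data. The adjustment is stricter with so few changed genes, so these shares do not measure the recovery in the data. In a simulation of 39 lists over 14873 genes, camera with the preset correlation called the 1 raised list and 0 of the others. Its genes were drawn independently. It therefore says nothing on false calls for correlated genes, and estimated correlations reached 0.87 in the lists here. Small changes were often missed in the simulation of single genes, and a gene that did not pass is not shown to be unchanged. Figures were drawn with matplotlib 3.10.9.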

Results

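The series compared gene expression in hepatocytes isolated from XCON mice, which carry floxed Xbp1 alleles, and XCKO mice, in which Xbp1 was deleted in hepatocytes. Xbp1 encodes a transcription factor of the unfolded protein response that becomes active when the endoribonuclease IRE1 splices its mRNA. All mice had been fed a high-fat diet for 26 weeks. Read counts per gene were available for 3 libraries per group, with total counts of 23919355 to 26502456 in XCON and 26477489 to 27240079 in XCKO. The first principal component of log2 CPM held 46.3% of the variance and separated the groups, with all XCON libraries below 0 and all XCKO libraries above it. Mitochondrial transcripts made up 22.8% of the counts in XCON 1, against 9.8% and 9.3% in XCON 2 and 3 and 9.6%, 9% and 13.1% in XCKO 1, 2 and 3, with 95% Wilson intervals, for counting error only, of at most 0.017 percentage points to either side. Globin transcripts reached 301.2 CPM in XCKO 1 and 700.4 CPM in XCKO 3, against 10 to 20.2 CPM in the other libraries.

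Xbp1 itself (ENSMUSG00000020484, protein-coding, mm10 chromosome 11, 5520659 to 5525893, plus strand) was lower in every XCKO library. Its counts were 4453, 8021 and 9434 in XCON 1, 2 and 3 and 1458, 1013 and 1558 in XCKO 1, 2 and 3. Xbp1 fell from 261 ± 79 CPM (SD, n = 3) to 55.2 ± 14 CPM (SD, n = 3). The log2 fold change was −2.24 ± 0.29 (SE), with an adjusted p of 0.0084 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the authors' deposited table it was −2.20, with an adjusted p of 4.77e-12. The deleted exons are not given in the sources used here, and reads from the rest of the transcript count toward the gene, so the remaining counts do not measure how much intact mRNA was left.

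As lists, genes for cytochrome P450 enzymes, fatty acid oxidation and the respiratory chain were higher in XCKO with the preset correlation between genes, and not with an estimated correlation (adjusted p = 0.35 for each), and the hepatocyte marker mean differed by 0.52 (XCKO minus XCON) beside them. Genes for protein folding in the endoplasmic reticulum (ER), interferon-stimulated genes, extracellular matrix and the cell cycle were lower with the preset correlation and not with an estimated one (adjusted p = 0.5, 0.42, 0.41 and 0.39). Apart from the respiratory chain, most members of each list did not pass, and the macrophage and stellate marker means differed by −1.16 and −1.05 (XCKO minus XCON) beside the falls. Past an adjusted p of 0.05 in edgeR's quasi-likelihood test were 1378 of 14873 genes, 775 higher and 603 lower in XCKO, and 654 of them changed more than 2-fold. In each of the 1378 genes the groups of 3 did not overlap, nor did they in 35.7% of all tested genes, where chance gives 10%. Scaling by library totals alone, chosen after seeing the data, gave 326 higher and 2032 lower genes (13.8% higher, against 56.2%) and moved the median log2 fold change of all genes from −0.05 to −0.31, a shift of −0.26. Fold changes here are relative to TMM scaling. The count fell to 489, 628 and 625 without XCON 1, 2 and 3 and to 684, 810 and 309 without XCKO 1, 2 and 3, and 228 genes (164 higher, 64 lower) passed in all 6 of these fits. The authors' deposited table called 2513 genes, 1361 higher and 1152 lower, and 1369 of the 1378 were among them in the same direction.

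**Figure D1:**
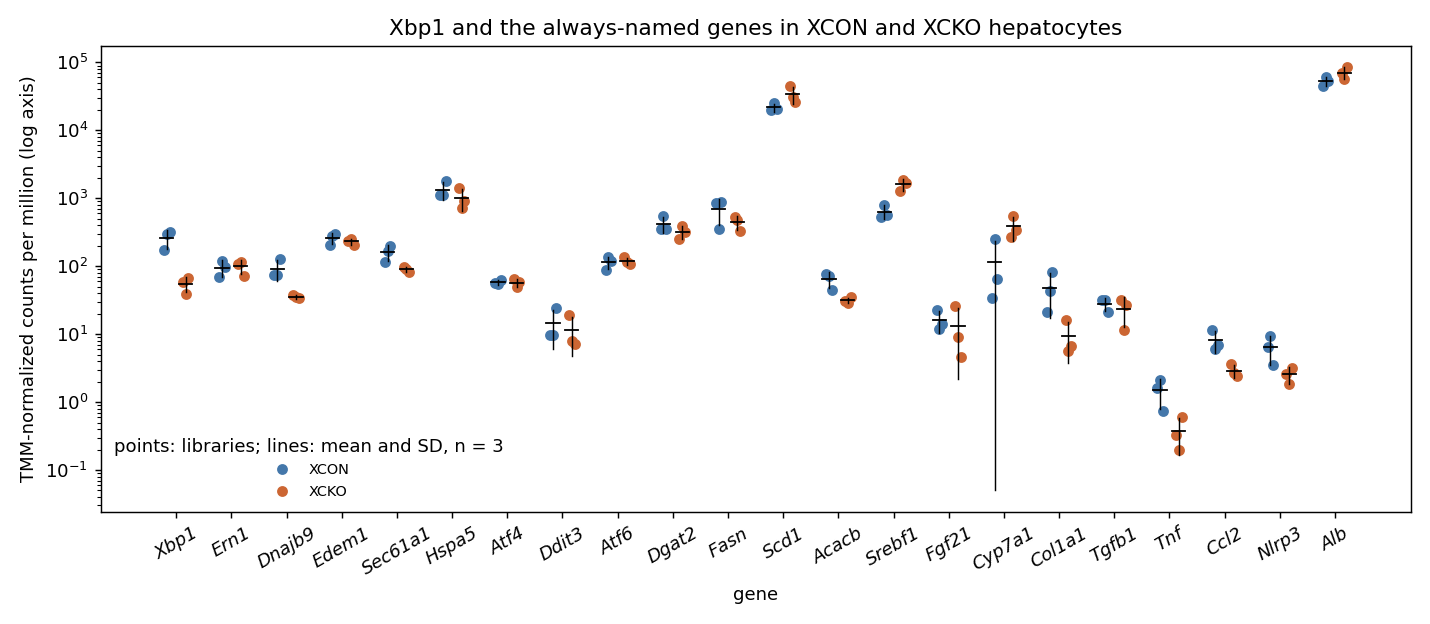
TMM-normalized CPM (log axis) of Xbp1 and the 21 genes named whatever their values, in the 3 XCON and 3 XCKO libraries. Points are libraries and lines the mean and SD (that of Cyp7a1 in XCON reaches below 0 and is drawn to 0.05), and Xbp1, Dnajb9, Sec61a1, Acacb and Ccl2 passed the test as lower, Srebf1 as higher and the other 16 not at all.

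Among the 12 genes with the largest rises, 3 were cytochrome P450 enzymes. Cyp2c29 (ENSMUSG00000003053, chromosome 19, 39269405 to 39330713) rose from 341 ± 72 to 2540 ± 430 CPM (SD, n = 3), a log2 fold change of 2.90 ± 0.25 (SE) with an adjusted p of 0.0018. Cyp2b9 rose by 3.01 and Cyp3a59 by 2.34. As members of large families of similar genes, Cyp2c29, Cyp2b9 and Cyp3a59 may share reads with paralogs and are uncertain. Cfd, which encodes the complement protease adipsin (ENSMUSG00000061780, chromosome 10, 79890853 to 79892655), had the largest log2 fold change of the 12, 5.71 ± 0.86 (SE), from 2.92 ± 2.3 to 153 ± 88 CPM (SD, n = 3) with an adjusted p of 0.021. Slc2a4, which encodes the insulin-responsive glucose transporter (ENSMUSG00000018566, chromosome 11, 69942539 to 69948188), rose from 3.35 ± 1.2 to 24.5 ± 1.8 CPM (SD, n = 3). The others were the laminin subunit gene Lamb3 (2.41), the ATP synthase subunit gene Atp5k (2.28), Aatk (2.24), the pseudogene Rpl7a-ps5 (2.16), Slc22a29 (2.07), Sema5b (2.02) and Leap2 (1.98), which encodes a liver-expressed antimicrobial peptide, each with its log2 fold change in brackets. Cfd did not pass without XCON 1 (adjusted p = 0.071), XCKO 1 or XCKO 3, and Slc22a29 did not pass without XCON 3 (0.078), XCKO 1 or XCKO 3, whereas the other 10 passed whichever library was left out.

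Cdh1, which encodes the adhesion protein E-cadherin (ENSMUSG00000000303, chromosome 8, 106603351 to 106670246), had the largest fall of the 12 lower genes, from 59.8 ± 22 to 2.53 ± 0.53 CPM (SD, n = 3). Its log2 fold change was −4.56 ± 0.31 (SE), a 23.6-fold difference, with an adjusted p of 0.0014 in edgeR's quasi-likelihood test. Ikbke, a kinase of innate immune signalling (ENSMUSG00000042349, chromosome 1, 131254343 to 131279606), fell from 48 ± 9.2 to 10.4 ± 0.55 CPM (SD, n = 3), and Unc13b (ENSMUSG00000028456, chromosome 4, 43058953 to 43264871) from 16.1 ± 1.7 to 2.28 ± 0.56 CPM (SD, n = 3). The growth factor gene Nrg1 had a log2 fold change of −2.62, Snhg11 −3.63, Xlr3a −2.68, the splicing regulator Srrm4 −2.17, and the interferon-induced genes Oas3 and Ifi209 −2.46 and −2.19. The pseudogene Mup-ps19 (−2.96) and the carboxylesterase Ces1g (−2.70) have close paralogs, as has Xlr3a, and their counts are uncertain. With Xbp1 the genes named in this paragraph are the 12. Snhg11 did not pass without XCKO 1 (adjusted p = 0.076) or XCON 1, Oas3 without XCKO 3 (0.076) or XCKO 2, and Ces1g without XCKO 3 (0.07) or any XCON library. Srrm4 did not pass without XCKO 2 (0.11) or any other library but XCON 2, nor Ifi209 without XCON 1 (0.11) or any other library but XCKO 2.

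Of 39 gene lists, 24 passed camera's adjusted p of 0.05 with the preset correlation, 12 higher and 12 lower in XCKO. None passed with the correlation estimated from the data, where the smallest adjusted p was 0.35 and 2 lists had an unadjusted p under 0.05. That setting tests on 4 residual degrees of freedom, which makes 0.05 hard to reach over 39 lists. The lipid droplet and uptake list, with an estimated correlation of 0.02 against the preset 0.01, went from an unadjusted camera p of 0.0066 to 0.061. For that list, failing to pass there is therefore not shown to come from correlation between genes. Estimated correlations were larger for macrophage markers (0.79), interferon-stimulated genes (0.41) and ER chaperone and degradation genes (0.36). Their unadjusted camera p went from 1.9e-06, 1e-07 and 0.00018 to 0.28, 0.16 and 0.28. There a larger correlation and fewer degrees of freedom acted together, and their shares were not separated. Each list is given below with its adjusted p from both settings. Expression differences also followed gene length. The median log2 fold change went from 0.21 in the decile of shortest genes to −0.25 in the decile of longest, and the shortest decile held 162 higher and 26 lower calls against 13 and 109 in the longest. After the length correction, chosen after seeing the data, 1083 genes passed (654 higher, 429 lower), 948 of them among the 1378, and 24 lists passed. The naming rule gave 121 genes past 0.05, of which 20 lost their call with this correction. Among these 20 were Ifi209 (adjusted p = 0.059), Sec61a1 (0.068), Acacb (0.058), Cyp8b1 (0.054) and Fbp1 (0.059). Others were G0s2 (0.054), Cideb (0.083), Lcat (0.086), Gpnmb (0.074) and Pdgfra (0.068).

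**Figure D2:**
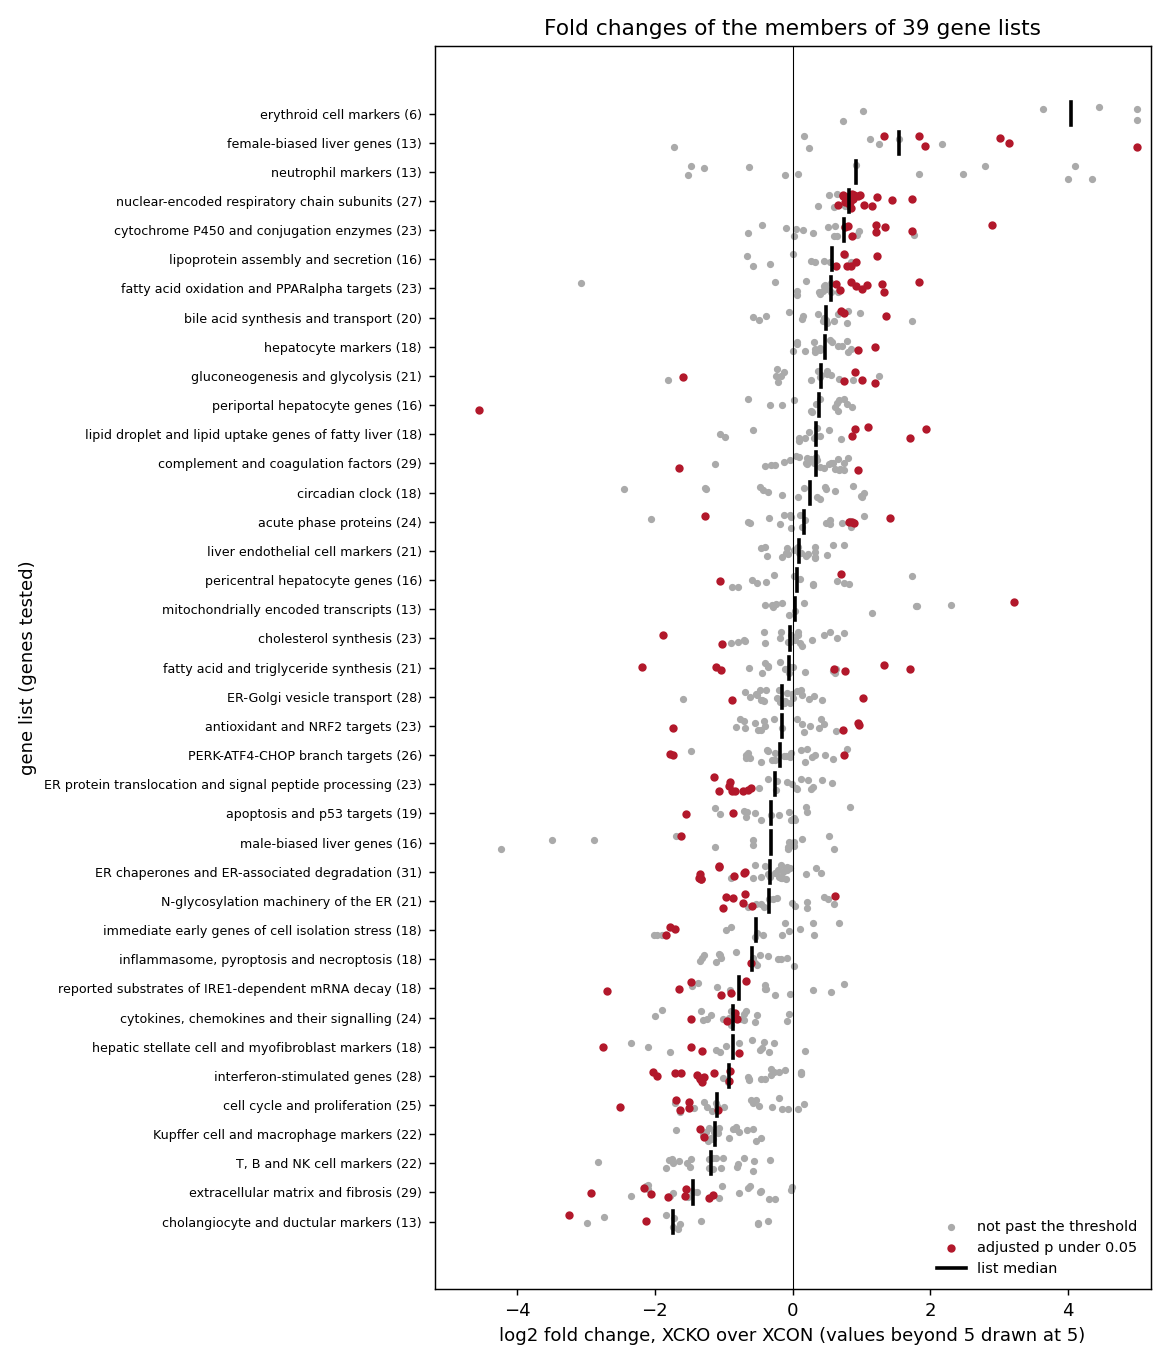
Log2 fold change (XCKO over XCON) of every tested member of the 39 lists, with the list median as a bar, members past an adjusted p of 0.05 in red, and values beyond 5, with the fitted value of Cyp3a16 that is no bound on its fold, drawn at 5. List medians ran from −1.73 for cholangiocyte markers to 4.05 for erythroid markers, and the medians of the cholesterol, acute phase, mitochondrially encoded, circadian, pericentral and endothelial lists changed sign or reached 0 under another scaling.

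**Figure D3:**
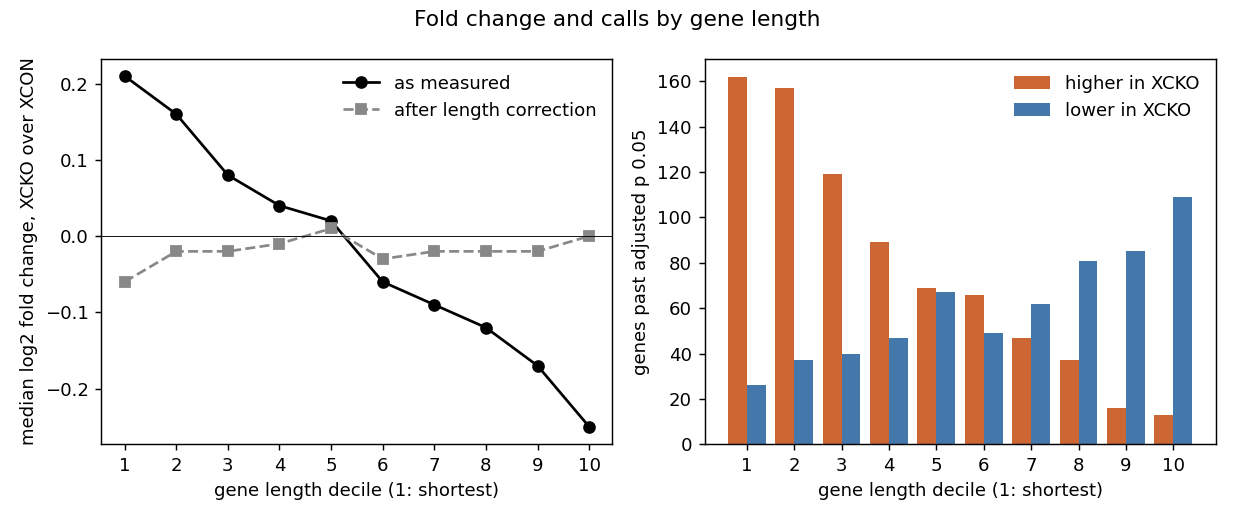
Median log2 fold change by decile of gene length (left, as measured and after the length correction) and the number of genes past an adjusted p of 0.05 in each direction (right). The median fell from 0.21 to −0.25 as measured and lay between −0.06 and 0.01 after the correction.

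Among genes that bring proteins into the ER and fold them there, some were lower in XCKO, and neither list passed with an estimated correlation. Of 23 genes for ER translocation and signal peptide processing, 0 were higher, 9 lower and 14 did not pass (2 higher and 10 lower adjusted over the list alone). The median log2 fold change was −0.25, with an adjusted p of 0.029 and an adjusted p = 0.5 with an estimated correlation. Tram1 fell from 178 ± 5.7 to 81 ± 3.9 CPM (SD, n = 3), and the Sec61 channel subunit genes Sec61b and Sec61g and the signal peptidase gene Sec11c had log2 fold changes of −0.89, −1.07 and −0.92. Sec61a1, the channel's main subunit, fell from 161 ± 42 to 90.4 ± 7.5 CPM (SD, n = 3). Of 31 ER chaperone and ER-associated degradation genes, 0 were higher, 9 lower and 22 did not pass (0 higher and 11 lower adjusted over the list alone). The list median was −0.33, with an adjusted p of 0.00049 and an adjusted p = 0.5 with an estimated correlation. Dnajb9, a co-chaperone, fell from 91.4 ± 30 to 35.7 ± 2.3 CPM (SD, n = 3), and Sdf2l1, Txndc11 and Dnajc10 had log2 fold changes of −1.33, −0.85 and −0.70. The translocation list did not pass without XCON 3, XCKO 1 or XCKO 2, where the largest adjusted p was 0.11. With 1 library left out, 3 to 5 translocation genes (fewest without XCON 3) and 1 to 8 folding genes (fewest without XCKO 3) were lower. Tram1, Sec61b and Sdf2l1 passed in all 6 of these fits, whereas Dnajb9 (adjusted p = 0.062) and Txndc11 (0.062) did not without XCKO 3, and Sec11c did not without XCON 1 (0.051). Dnajc10 passed in 3 of the 6 fits and Sec61g in 2. Sec61a1 passed only without XCON 1 and had its largest adjusted p, 0.13, without XCKO 3.

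Of the genes of the 3 sensors of the unfolded protein response, 1 passed. Eif2ak3, which encodes PERK and was chosen after its values were seen, fell from 36.8 ± 5.9 to 17.2 ± 2.7 CPM (SD, n = 3), a log2 fold change of −1.09 ± 0.17 (SE) with an adjusted p of 0.013 (0.054 without XCKO 3 and under 0.05 without any other library). Ern1, which encodes IRE1, had 95.2 ± 27 CPM in XCON and 99.2 ± 23 in XCKO (SD, n = 3), Atf6 had 114 ± 23 and 119 ± 15, and Atf4 had 58 ± 4.8 and 57.4 ± 7.5, none past the test. Neither did Hspa5, Edem1 or Ddit3 pass. The chaperone gene Hspa5 had a log2 fold change of −0.40 ± 0.30 (SE), Edem1 −0.19 ± 0.19 and Ddit3, which encodes CHOP, −0.35 ± 0.50. The hepatokine gene Fgf21, a target of this response and of PPARα, had 16.2 ± 5.8 and 13.2 ± 11 CPM (SD, n = 3) with an adjusted p of 0.78. Among 26 targets of the PERK branch, 1 was higher (Eif4ebp1, 0.74), 2 were lower (Slc7a11, −1.73, and Atf3, −1.78) and 23 did not pass (3 higher and 4 lower adjusted over the list alone). Their median was −0.18 and their adjusted p 0.79 (0.89 with an estimated correlation). The N-glycosylation list had 1 higher, 6 lower and 14 not passing of 21 (3 higher and 9 lower adjusted over the list alone). These genes had a median of −0.34 and an adjusted p of 0.096 (0.62 with an estimated correlation). Its oligosaccharyltransferase genes Ostc, Magt1 and Ddost had log2 fold changes of −0.97, −0.86 and −0.69, and Alg5 rose by 0.61. Of 28 ER-Golgi transport genes, Sar1b rose by 1.03, Sec23b had a log2 fold change of −0.88 and 26 did not pass (1 higher and 2 lower adjusted over the list alone). The median of the list was −0.15 and its adjusted p 0.16 (0.67 with an estimated correlation). Under total-count scaling 11 glycosylation, 8 transport and 5 PERK target genes were lower. With the filter of 5 CPM, the glycosylation (adjusted p = 0.032) and transport (0.047) lists passed as lower. The glycosylation list had an adjusted p of 0.047 without XCON 1 and 0 (without XCON 3) to 2 lower members with 1 library left out. Each called gene in this paragraph lost its call without at least 1 library, Eif4ebp1 only without XCKO 3 (adjusted p = 0.053), Sar1b without XCON 2, XCON 3 (0.062) or XCKO 3, and Slc7a11, Atf3, Sec23b, Ostc, Magt1, Ddost and Alg5 in 4 or more of the 6 fits, with the largest adjusted p, 0.12, for Slc7a11 without XCON 1.

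Of 18 tested genes reported as substrates of IRE1-dependent mRNA decay, 0 were higher, 6 lower and 12 did not pass (1 higher and 7 lower adjusted over the list alone). The median was −0.78, with an adjusted p of 0.0025 and an adjusted p = 0.4 with an estimated correlation. The carboxylesterase gene Ces1e fell from 117 ± 6.3 to 62.6 ± 8.4 CPM (SD, n = 3), a log2 fold change of −0.90, and Ces1g and the growth factor receptor gene Pdgfrb had log2 fold changes of −2.70 and −1.48. Ces1e and Ces1g have close paralogs that may share reads, and their counts are uncertain. Pdgfrb is also a stellate marker, and the stellate marker mean differed by −1.05 (XCKO minus XCON). Dgat2, the final enzyme of triglyceride synthesis and a member of this list, had 417 ± 110 and 318 ± 68 CPM (SD, n = 3) with an adjusted p of 0.31. With 1 library left out, 2 (without XCON 2) to 6 members were lower, and Ces1e passed in all 6 fits. Ces1g did not pass without XCKO 3 (adjusted p = 0.07) or any XCON library, nor Pdgfrb without XCKO 3 (0.061), XCON 2 or XCON 3.

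Lipid synthesis genes moved both ways. Of 21 genes of fatty acid and triglyceride synthesis, 4 were higher, 3 lower and 14 did not pass (6 higher and 3 lower adjusted over the list alone). Srebf1, which encodes the main transcription factor of lipogenesis, rose from 638 ± 150 to 1600 ± 300 CPM (SD, n = 3), and Thrsp rose by 1.70. The acetyl-CoA carboxylase gene Acacb and the desaturase gene Fads1 had log2 fold changes of −1.05 and −1.12. Fasn (−0.63 ± 0.35, SE) and Scd1 (0.63 ± 0.27, SE) did not pass. The list's median (−0.05) and mean (−0.02) lay below 0 and camera's direction was up, with an adjusted p of 0.45 (0.63 with an estimated correlation). Of 23 cholesterol synthesis genes, Cyp51 (−1.03) and Idi1 (−1.89) fell, 0 rose and 21 did not pass (1 higher and 3 lower adjusted over the list alone). Their median was −0.03, which reached 0 with size factors, and the adjusted p was 0.5 (0.68 with an estimated correlation). Under total-count scaling 7 cholesterol genes were lower, and 2 synthesis genes higher and 3 lower. Thrsp and Cyp51 passed in all 6 fits without 1 library, and Srebf1 did not without XCON 3 or XCKO 3 (adjusted p = 0.055). Acacb passed only without XCON 3 (0.066 without XCON 1), Fads1 only without XCON 3 or XCKO 2 (0.07 without XCKO 3), and Idi1 did not without XCON 3, XCKO 1 or XCKO 3 (0.075).

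Some fatty acid oxidation and PPARα target genes were higher in XCKO, and the list did not pass with an estimated correlation. Of 23, 9 rose, 0 fell and 14 did not pass (13 higher and 1 lower adjusted over the list alone). The list median was 0.56, with an adjusted p of 9.7e-07 and an adjusted p = 0.35 with an estimated correlation. Fabp1, which binds fatty acids in the cytosol, rose from 458 ± 32 to 1130 ± 140 CPM (SD, n = 3), and Cyp4a14, Acadvl and Acaa1b rose by 1.84, 1.01 and 1.08. Of 18 lipid droplet and uptake genes, 5 rose, 0 fell and 13 did not pass (6 higher and 1 lower adjusted over the list alone). Their median was 0.34, with an adjusted p of 0.012 and an adjusted p = 0.35 with an estimated correlation. Fitm1 rose from 13.3 ± 0.75 to 51.2 ± 1.9 CPM (SD, n = 3), the lipase inhibitor gene G0s2 by 1.70, Mogat1 by 1.10 and Cideb by 0.90. Under total-count scaling 5 oxidation genes were higher and 0 lower, and 2 droplet genes were higher and 2 lower, with a droplet median of 0.07. After the length correction the droplet list had 1 higher member and an adjusted p of 0.056, and without XCKO 1 its adjusted p was 0.076. With 1 library left out, 2 to 5 oxidation genes (fewest without XCON 2) and 1 to 4 droplet genes (fewest without XCON 3) were higher. Fabp1, Cyp4a14 and Fitm1 passed in all 6 fits, and Acadvl, Acaa1b, G0s2, Mogat1 and Cideb in 1 or 2, with the largest adjusted p, 0.11, for G0s2 without XCON 1.

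Lipoprotein, bile acid and glucose genes were also higher as lists with the preset correlation and not with an estimated one, beside a hepatocyte marker mean that differed by 0.52 (XCKO minus XCON). Of 16 lipoprotein genes, 6 rose, 0 fell and 10 did not pass (9 higher and 0 lower adjusted over the list alone). These genes had a median of 0.58, with an adjusted p of 0.00028 and an adjusted p = 0.41 with an estimated correlation. Apoe rose from 20100 ± 2700 to 46900 ± 2700 CPM (SD, n = 3), and Lcat, Tm6sf2 and Lipc rose by 0.84, 0.78 and 0.63. Of 20 bile acid genes, 3 rose, 0 fell and 17 did not pass (4 higher and 0 lower adjusted over the list alone). The median of the list was 0.49, with an adjusted p of 0.00049 and an adjusted p = 0.35 with an estimated correlation. Cyp8b1, Slco1a4 and Cyp27a1 rose by 1.35, 0.74 and 0.70, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 117 ± 120 and 388 ± 150 CPM (SD, n = 3) with an adjusted p of 0.19. Of 21 gluconeogenesis and glycolysis genes, 4 rose, 1 fell and 16 did not pass (8 higher and 1 lower adjusted over the list alone). The list median was 0.42, with an adjusted p of 0.0069 and an adjusted p = 0.47 with an estimated correlation. The gluconeogenic genes Pcx and Fbp1 rose by 1.19 and 1.01 and the glycolytic Pfkl by 0.90, while Pfkfb3 had a log2 fold change of −1.59. The higher members numbered 0 to 2, 0 to 2 and 1 to 4 in the 3 lists when 1 library was left out (fewest without XCON 3, XCON 1 and XCON 1), and 1, 1 and 2 both after the length correction and under total-count scaling. The medians under total-count scaling were 0.32, 0.23 and 0.14. The calls of Cyp8b1, Slco1a4 and Cyp27a1 were all lost without XCON 2 as well as without XCON 1. Pcx and Pfkfb3 passed in all 6 fits. Cyp8b1 did not pass without XCON 1 (adjusted p = 0.08) or XCON 2, nor Apoe without XCON 3, XCKO 1 or XCKO 3 (0.068). The other genes named as higher passed in at most 2, with the largest adjusted p, 0.11, for Tm6sf2 without XCKO 3.

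Cytochrome P450 and conjugation enzymes rose in 8 of 23 cases, fell in 0 and did not pass in 15 (9 higher and 0 lower adjusted over the list alone). The median was 0.75, with an adjusted p of 4.3e-06 and an adjusted p = 0.35 with an estimated correlation. Cyp3a11, a major drug-metabolizing enzyme, rose from 3140 ± 540 to 10500 ± 1500 CPM (SD, n = 3), and Cyp3a25, Ces2a and Cyp2c29 by 1.35, 1.21 and 2.90. Those 4 passed in all 6 fits without 1 library. These fits held 4 (without XCON 1) to 7 higher members of the list, and 5 were higher after the length correction. Of 13 tested female-biased liver genes (20 in the list), 6 rose, 0 fell and 7 did not pass (7 higher and 0 lower adjusted over the list alone). Their median was 1.54, with an adjusted p of 2.2e-05 and an adjusted p = 0.35 with an estimated correlation. Cyp3a16 had no read in XCON and 198, 168 and 80 in XCKO 1, 2 and 3, at least 55.1-fold higher against a floor of 3 counts per library (0.109 CPM, counting error only), and the list median with that bound was also 1.54. Cyp3a16 passed the filter on low counts only through XCKO, where it was high. With no such filter, 7 members of the list were higher and 0 lower. Hao2 rose by 3.15. Of 16 male-biased genes, Mup20 fell, from 3400 ± 510 to 1110 ± 340 CPM (SD, n = 3), 0 rose and 15 did not pass (0 higher and 1 lower adjusted over the list alone). These genes had a median of −0.32 and an adjusted p of 0.31 (0.82 with an estimated correlation). Cyp3a, Cyp2b and Mup genes have near-identical copies and Cyp2c genes close paralogs, so the counts of all these genes are uncertain. Hao2 did not pass without XCON 2 (adjusted p = 0.058), and 4 to 5 female-biased genes rose when 1 library was left out. The male-biased list had an adjusted p of 0.00025, as lower, without XCON 1 and did not pass without any other library.

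Nuclear-encoded respiratory chain subunits had the smallest p of the 39 lists with the preset correlation, though not with an estimated one. Of 27, 22 rose, 0 fell and 5 did not pass (26 higher and 0 lower adjusted over the list alone). The median of the list was 0.82, with an adjusted p of 1.2e-15 and an adjusted p = 0.35 with an estimated correlation. The complex I genes Ndufa2, Ndufb8, Ndufb3 and Ndufa1 rose by 1.73, 1.23, 1.16 and 1.45, Ndufa2 from 19.8 ± 3.2 to 65.5 ± 14 CPM (SD, n = 3), and these passed in all 6 fits without 1 library. The higher members numbered 6 to 18 when 1 library was left out, the fewest without XCKO 3, 17 after the length correction, and 10, with a median of 0.55, under total-count scaling. Of 13 mitochondrially encoded transcripts, mt-Atp8 rose by 3.21, 0 fell and 12 did not pass (1 higher and 0 lower adjusted over the list alone). Their median was 0.04 and their adjusted p 0.062 (0.68 with an estimated correlation), and the median was −0.24 under total-count scaling and −0.18 after the length correction. That list passed without XCON 1, the library with the largest mitochondrial share (adjusted p = 1e-05), without XCKO 2 (0.015), under total-count scaling (0.0056) and with no filter on low counts (0.011), each time with camera's direction up. mt-Atp8 (0.647 ± 0.24 and 6.03 ± 2.2 CPM, SD, n = 3) overlaps mt-Atp6 and is uncertain. Of 23 antioxidant genes, 3 rose (Sod1, 0.96, Sod2, 0.74, and Mgst3, 0.96), Slc7a11 fell and 19 did not pass (3 higher and 1 lower adjusted over the list alone). The median was −0.16 and the mean −0.10 while camera's direction was up, with an adjusted p of 0.7 (0.89 with an estimated correlation), and after the length correction it was down (0.81). Under total-count scaling 1 antioxidant gene was higher and 4 were lower. Sod1 passed in 3 of the 6 fits without 1 library, Sod2 in 2 and Mgst3 in 1 (0.1 without XCON 2).

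Interferon-stimulated genes fell in 12 of 28 cases, rose in 0 and did not pass in 16 (0 higher and 19 lower adjusted over the list alone). The median was −0.92, with an adjusted p of 1e-06 and an adjusted p = 0.42 with an estimated correlation. The antiviral genes Oas2 and Ifit2 had log2 fold changes of −2.03 and −1.62 and the guanylate-binding protein genes Gbp2 and Gbp3 −1.35 and −1.32. Of 24 cytokine and chemokine genes, 4 fell, 0 rose and 20 did not pass (0 higher and 14 lower adjusted over the list alone). The list median was −0.87, with an adjusted p of 2.1e-06 and an adjusted p = 0.35 with an estimated correlation. The chemokine gene Ccl2 fell from 8.1 ± 2.9 to 2.9 ± 0.62 CPM (SD, n = 3), and Tlr2, Cxcl10 and Birc3 had log2 fold changes of −0.95, −0.84 and −0.80. Tnf had 1.5 ± 0.7 and 0.374 ± 0.21 CPM (SD, n = 3) with an adjusted p of 0.062. Of 18 inflammasome and cell death genes, Casp8 fell (−0.60), 0 rose and 17 did not pass (0 higher and 6 lower adjusted over the list alone). Their median was −0.59, with an adjusted p of 0.00021 and an adjusted p = 0.35 with an estimated correlation. Nlrp3 had a log2 fold change of −1.35 ± 0.39 (SE) and an adjusted p of 0.06. The macrophage marker mean differed by −1.16 (XCKO minus XCON) beside these lists. Under total-count scaling 20 interferon, 15 cytokine and 10 inflammasome genes were lower. Without 1 library, 1 to 10 interferon genes (fewest without XCKO 3), 0 to 4 cytokine genes and 0 to 1 inflammasome genes (fewest of both without XCON 1) were lower. The calls of Ccl2, Tlr2, Cxcl10 and Birc3 were all lost without XCKO 2 and without XCKO 3 as well. Gbp2 passed in all 6 fits, and Oas2, Ifit2 and Gbp3 did not without XCKO 3 (adjusted p = 0.058, 0.068 and 0.054). Ccl2 did not pass without XCON 1, XCKO 2 or XCKO 3 (0.084). Tlr2, Cxcl10 and Birc3 passed in 1 fit each, and Casp8 did not pass in any (0.061 to 0.072).

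Some extracellular matrix and cell cycle genes were lower as well, and neither list passed with an estimated correlation. Of 29 matrix genes, 8 fell, 0 rose and 21 did not pass (0 higher and 18 lower adjusted over the list alone). These genes had a median of −1.44, with an adjusted p of 1.5e-07 and an adjusted p = 0.41 with an estimated correlation. Timp2, an inhibitor of matrix metalloproteinases, fell from 19.4 ± 3.3 to 8.7 ± 1.7 CPM (SD, n = 3), and Timp1, the collagen-crosslinking enzyme gene Lox and Col5a2 had log2 fold changes of −2.16, −2.93 and −1.21. Col1a1 had 48.3 ± 31 and 9.48 ± 5.7 CPM (SD, n = 3) with an adjusted p of 0.063, and Tgfb1 28.2 ± 6 and 23.7 ± 11 CPM with an adjusted p of 0.67. The stellate marker mean differed by −1.05 (XCKO minus XCON). Of 25 cell cycle genes, 6 fell, 0 rose and 19 did not pass (0 higher and 15 lower adjusted over the list alone). The median of the list was −1.10, with an adjusted p of 1.5e-06 and an adjusted p = 0.39 with an estimated correlation. Cyclin D1 (Ccnd1) fell from 34.7 ± 5.6 to 10.7 ± 1.3 CPM (SD, n = 3), and Top2a, Bub1 and Cdk1 had log2 fold changes of −1.64, −2.50 and −1.51. Of 19 apoptosis and p53 genes, Mdm2 (−0.86) and Phlda3 (−1.55) fell, 0 rose and 17 did not pass (0 higher and 2 lower adjusted over the list alone). The list median was −0.31 and its adjusted p 0.096 (0.47 with an estimated correlation). Under total-count scaling 18 matrix, 16 cell cycle and 6 apoptosis genes were lower, and after the length correction 5, 5 and 2. With 1 library left out, 1 to 9 matrix genes (fewest without XCKO 3) and 3 to 7 cell cycle genes (fewest without XCON 1) were lower, and the apoptosis list had an adjusted p of 0.045 without XCON 2 and of 0.025 after the length correction. Timp2, Ccnd1, Top2a and Bub1 passed in all 6 fits, and Timp1 (adjusted p = 0.058) and Lox (0.055) did not without XCKO 3. Mdm2 passed in 2, Cdk1 and Col5a2 in 1 each (0.092 for Col5a2 without XCON 3) and Phlda3 not in any (0.052 to 0.093).

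Genes of secreted plasma proteins moved both ways. Of 24 acute phase genes, 4 rose, 1 fell and 19 did not pass (7 higher and 2 lower adjusted over the list alone), with a median of 0.16 that was −0.11 under total-count scaling, an adjusted p of 0.048 and an adjusted p = 0.63 with an estimated correlation. Saa4 rose by 1.42, Lbp by 0.89 and Serpina3m by 0.82, and the interleukin-1 receptor antagonist gene Il1rn had a log2 fold change of −1.27. That list passed in 2 of the 6 fits without 1 library, with an adjusted p of 0.17 without XCON 1 and none under 0.05 without XCON 2, XCKO 1 or XCKO 3, and had an adjusted p of 0.19 after the length correction, 0.13 with the filter of 5 CPM and 0.056 with size factors. Under total-count scaling 2 of its genes were higher and 3 lower. Of 29 complement and coagulation genes, C8g rose by 0.96, Hc, which encodes complement C5, fell from 1350 ± 420 to 430 ± 80 CPM (SD, n = 3), and 27 did not pass (4 higher and 1 lower adjusted over the list alone). Their median was 0.34, with an adjusted p of 0.0025, an adjusted p = 0.63 with an estimated correlation and 0.12 without XCON 1. Of 18 immediate early genes, 0 rose, 3 fell and 15 did not pass (1 higher and 4 lower adjusted over the list alone). Their median was −0.53 and their adjusted p 0.055 (0.63 with an estimated correlation). Atf3, Egr2 and Klf6 had log2 fold changes of −1.78, −1.84 and −1.71. That list passed without XCON 1, XCON 2 (adjusted p = 0.013), XCKO 1 or XCKO 3 and had an adjusted p of 0.46 without XCON 3. It also passed with size factors (0.045), no filter on low counts (0.044) and the length correction (0.019), and under total-count scaling 5 of its genes were lower. Saa4 and Il1rn passed in all 6 fits without 1 library, and Hc did not without XCKO 3 (0.061). C8g passed in 3, Lbp in 2 and Serpina3m, Atf3, Egr2 and Klf6 in 1 each (0.16 for Klf6 without XCKO 2). The 18 circadian clock genes held 0 calls by edgeR's quasi-likelihood test (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom). With 1 library left out, 0 to 2 of them were higher. Their median of 0.26 was 0 under total-count scaling, and the list had an adjusted p of 0.42 (0.67 with an estimated correlation).

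Hepatocyte zonation and marker lists were compared next. Of 16 pericentral genes, 1 rose (Cyp27a1), the glutamine synthetase gene Glul fell (−1.05) and 14 did not pass (3 higher and 2 lower adjusted over the list alone), with a median of 0.06 that was −0.19 under total-count scaling and an adjusted p of 0.5 (0.82 with an estimated correlation). Of 16 periportal genes, Cdh1 fell, 0 rose and 15 did not pass (0 higher and 1 lower adjusted over the list alone). These genes had a median of 0.38 and an adjusted p of 0.096 (0.67 with an estimated correlation). Of 18 hepatocyte markers, Hpd (1.20) and Asgr1 (0.95) rose, 0 fell and 16 did not pass (7 higher and 0 lower adjusted over the list alone). The median of the list was 0.47, with an adjusted p of 5.6e-05 and an adjusted p = 0.41 with an estimated correlation. Alb, which encodes albumin, had 53800 ± 8200 and 70800 ± 14000 CPM (SD, n = 3) with an adjusted p of 0.34. Of the hepatocyte markers, 0 (without XCKO 3) to 2 were higher with 1 library left out, and Hpd did not pass without XCON 2 or XCKO 3 (adjusted p = 0.068), nor Asgr1 without XCON 1, XCON 3 or XCKO 3 (0.068). Glul passed only without XCKO 3 (0.1 without XCKO 2), and the periportal list passed without XCON 3 (0.035) and XCKO 1 (0.0075) and with no filter on low counts (0.029), as higher.

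Markers of other liver cells moved in different directions. Of the tested markers, 4 stellate, 2 cholangiocyte and 4 hepatocyte genes also belong to another list, and no macrophage or endothelial gene does. Of 22 macrophage markers, Cd68 and Gpnmb fell, 0 rose and 20 did not pass (0 higher and 8 lower adjusted over the list alone). The list median was −1.12, with an adjusted p of 9.3e-06 and an adjusted p = 0.5 with an estimated correlation. Cd68 fell from 55.3 ± 14 to 21.8 ± 7.8 CPM (SD, n = 3). Of 18 stellate cell markers, Lrat, Acta2, Pdgfra and Pdgfrb fell, 0 rose and 14 did not pass (0 higher and 8 lower adjusted over the list alone). Their median was −0.87, with an adjusted p of 5.4e-05 and an adjusted p = 0.5 with an estimated correlation. Of 13 cholangiocyte markers, Bicc1 and Tspan8 fell, 0 rose and 11 did not pass (0 higher and 5 lower adjusted over the list alone). These genes had a median of −1.73, with an adjusted p of 0.00087 and an adjusted p = 0.41 with an estimated correlation. None of 22 lymphocyte markers passed in edgeR's quasi-likelihood test, over all genes or adjusted over the list alone (6 were lower at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom), and Trbc2 had the smallest p (log2 fold change −2.83). Their median was −1.18, with an adjusted p of 0.0028, an adjusted p = 0.63 with an estimated correlation and 0.071 without XCON 1. The 21 endothelial markers held 0 edgeR calls (0 adjusted over the list alone, 2 higher at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom), with a median of 0.10 that was −0.17 under total-count scaling and an adjusted p of 0.64 (0.89 with an estimated correlation), and Tie1 had the smallest p (log2 fold change 0.59). The 13 neutrophil markers also held 0 edgeR calls (0 adjusted over the list alone, 3 higher and 2 lower at an unadjusted p under 0.05, 2 and 2 by DESeq2, 0 and 1 by limma-voom), with a median of 0.92 and an adjusted p of 0.51 (0.89 with an estimated correlation), and Wfdc21 had the smallest p (log2 fold change 0.92). Without XCKO 2, the endothelial list (adjusted p = 0.0086) and the neutrophil list (0.0014) passed as higher. Of 6 erythroid markers, 0 passed over all genes by edgeR or limma-voom, and 5 were higher adjusted over the list alone, at an unadjusted p under 0.05 and by DESeq2, with a median of 4.05, an adjusted p of 0.0069 and an adjusted p = 0.5 with an estimated correlation, and Alas2 had the smallest p (log2 fold change 1.02).

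Calls of markers depended on the scaling, the filter and the libraries. Under total-count scaling 13 macrophage, 9 stellate, 5 cholangiocyte, 3 lymphocyte and 2 neutrophil markers were lower, and after the length correction 1, 3, 3, 0 and 0. With the filter of 5 CPM the cholangiocyte (adjusted p = 0.067) and lymphocyte (0.058) lists did not pass. With 1 library left out, 0 to 5 macrophage markers (fewest without XCON 1), 0 to 5 stellate markers (fewest without XCON 3) and 0 to 4 cholangiocyte markers (fewest without XCKO 1) were lower. The calls of the stellate markers Lrat, Acta2, Pdgfra and Pdgfrb were all lost without XCKO 3 as well. Of the erythroid markers, 0 to 5 were higher in these fits. Cd68 did not pass without XCON 1, XCON 2 or XCKO 1 (adjusted p = 0.081), and Gpnmb passed only without XCKO 3 (0.11 without XCKO 2). Bicc1 did not pass without XCON 1, XCKO 1 or XCKO 3 (0.084), nor Tspan8 without any 1 of the XCKO libraries (0.084 without XCKO 3). Lrat and Pdgfra passed in 1 of 6 fits and Acta2 in 2, with the largest adjusted p, 0.11, for Pdgfra without XCKO 3.

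Averaged per library, 5 of 13 lists separated the groups without overlap. The gap was small for the stellate mean, 3.66 in XCKO 1 against 3.69 in XCON 1, and the macrophage mean, 5.32 in XCKO 3 against 5.4 in XCON 3. The XCKO minus XCON difference in mean log2 CPM was 1.74 for female-biased genes, 0.52 for hepatocyte, −1.16 for macrophage, −1.05 for stellate and −1.40 for cholangiocyte markers, each with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows, and an adjusted p of 0.26. Endothelial markers differed by 0.03 (exact p = 0.8) and lymphocyte markers by −1.09 (exact p = 0.2). The erythroid mean was 5.40 in XCKO 1 and 6.38 in XCKO 3 against 2.25 in XCKO 2 and 1.80 to 2.34 in XCON.

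**Figure D4:**
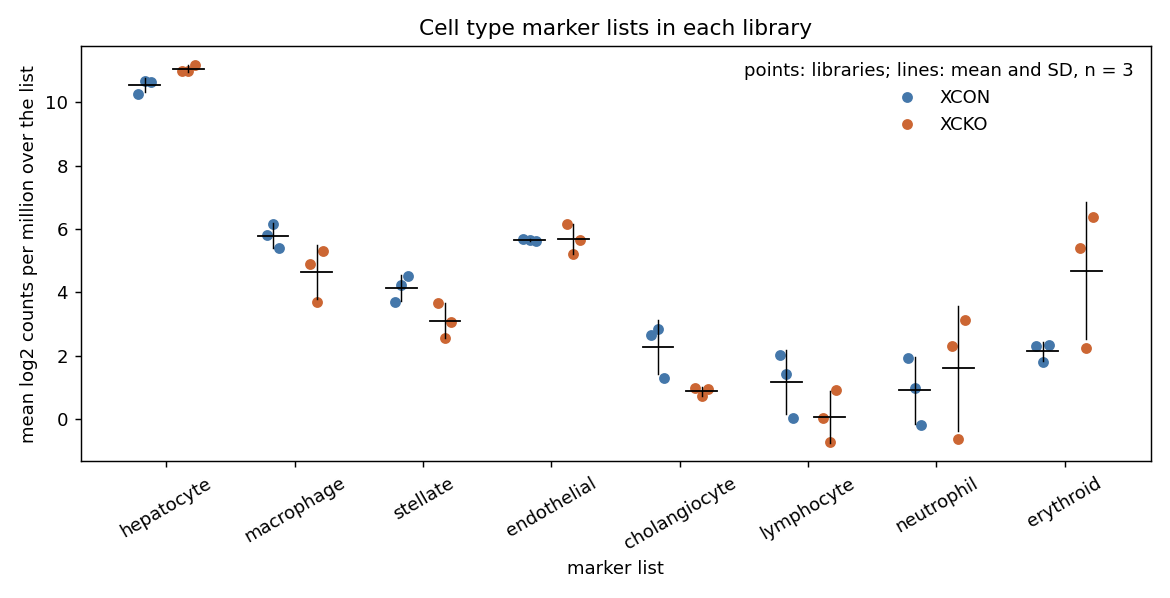
Mean log2 CPM of each cell type marker list in the 3 XCON and 3 XCKO libraries, with points as libraries and lines as mean and SD. Macrophage, stellate and cholangiocyte means were lower and hepatocyte means higher in every XCKO library than in any XCON library, while endothelial means overlapped. The gap was small for stellate (3.66 in XCKO 1, 3.69 in XCON 1) and macrophage means (5.32 in XCKO 3, 5.4 in XCON 3).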

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

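The scaling by library totals and the correction for gene length were chosen after the data were seen, and the other alternatives were set beforehand. The 1378 genes became 2160 (1185 higher, 975 lower) with no filter on low counts, where 26604 genes were tested, and 2538 (1375 higher, 1163 lower) with DESeq2, 1369 of them among the 1378. DESeq2 gave no adjusted p to 6 of the 1378. With the replicate number as a block 322 passed (220 higher, 102 lower), 307 of them among the 1378. Of the 121 genes past 0.05 given by the naming rule, 64 lost their call with the block. The labels do not say whether the numbers pair the samples. Deviations from the group mean correlated at 0.06, 0.08 and −0.17 (across genes) between libraries of the same number. Between libraries of different number and group they correlated at −0.16 to 0.11. These values give no sign of pairing, but so few pairs cannot exclude it, and a block takes residual degrees of freedom. The block also gave calls to the mitochondrially encoded (adjusted p = 0.047), immediate early (0.0084) and periportal (0.033) lists and ended that of the acute phase list (0.062). Scaling by library totals gave 2358 genes (326 higher, 2032 lower). Limma on log2 FPKM, over 10965 genes, gave 890 higher and 335 lower genes with a pseudocount of 1 (72.7% higher, against 56.2%) and 843 higher and 289 lower with 0.1 (74.5% higher). Leaving out 1 library gave 309 to 810 genes, 178 to 523 higher and 131 to 287 lower, with fewer samples tested, and 228 of the 1378 passed in every such fit. With the correlation between genes estimated, and the 4 residual degrees of freedom used with it, 0 lists passed. Except where the construction of an alternative is given, the cause was not tested. Size factors (1427 genes), the stricter filter (1308), limma-voom (1454) and the length correction (1083) stayed within 1.5 times the count. Xbp1 stayed lower under every alternative, with a log2 fold change of −2.53 to −2 and an adjusted p of 4.7e-12 to 0.04, the largest with the block. Between 23 and 27 lists passed under the alternatives other than the estimated correlation, and 4 to 7 marker lists separated the groups without overlap under the other scalings and without 1 library. Single genes and lists stayed on the same side of the threshold in 2213 comparisons with an alternative, where some that were not past it changed sign (Ddit3 lay between −0.93 and 0.24 without 1 library), lost their call in 452, gained one in 52 and reversed, changing sign with a call on either side, in 0. The simulation, with far fewer changed genes than were called in the data, recovered 4% of genes changed 1.5-fold and 18.4% of those changed 2-fold. These shares do not measure the recovery in the data. Neither depth nor the number of libraries was varied in the simulation.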

Other observations

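The difference between macrophage and endothelial means, the comparison of female-biased genes with lists matched for length, the scaling by library totals, the correction for gene length and the tests of gene families were chosen only after the results they bear on had been seen.

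The rise of nuclear-encoded respiratory chain genes was set against 10000 random lists matched for expression and for gene length or GC content. The list median of 0.82 exceeded the mean of lists matched for length (0.35) by 0.47 and that of lists matched for GC content (0.17) by 0.65, and lay above the highest of either kind (0.76 and 0.59). Lists matched for length or for GC content thus did not reach the list median. Their genes were drawn independently, so their range leaves out correlation between members, estimated at 0.54 for this list. Length and GC content were not matched jointly. After the length correction 17 members passed rather than 22, with a median of 0.77. A higher mRNA level of these genes in hepatocytes and a larger share of hepatocytes in the XCKO preparations both stay open, since the hepatocyte marker mean differed by 0.52 and the macrophage, stellate and cholangiocyte means by −1.16, −1.05 and −1.40 (XCKO minus XCON). Open remain also the correlation between these genes, with an adjusted p = 0.35 when it is estimated from the data, and differences between preparations that follow the groups.

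The fall of macrophage markers was also set against gene length and against a lower share of non-hepatocyte cells of every type. The median of −1.12 differed by −1.38 from the mean of lists matched for length (0.27), whose lowest was −0.33. The matched genes were drawn independently, so that range leaves out correlation between members, estimated at 0.79 for the macrophage list. A lower share of every other cell type would lower macrophage and endothelial markers alike. The macrophage minus endothelial mean was 0.13, 0.53 and −0.23 in XCON 1, 2 and 3 and −1.26, −1.54 and −0.33 in XCKO 1, 2 and 3. The groups differed by −1.19 or −2.3 pooled SDs (two-sided exact permutation p = 0.1, the smallest possible). Endothelial markers, whose mean differed by 0.03, were chosen after that was seen. The stellate, cholangiocyte and lymphocyte means differed by −1.05, −1.40 and −1.09 (XCKO minus XCON), beside −1.16 for macrophages. The comparison therefore bears only on a loss that includes endothelial cells. Fewer macrophages in the XCKO preparations, alone or with other cell types, may explain the fall, as may less mRNA of these genes per macrophage. Neither was tested apart from the other. GC content was not tested for this list, and its adjusted p = 0.5 with an estimated correlation.

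The rise of female-biased genes was set against the sex of the animals and gene length. In 6 of 6 libraries Xist was under 1 CPM (at most 0.25) and 4 Y-linked genes summed to 94.2 to 155 CPM, so that more females in XCKO is excluded by these transcripts. The list median of 1.54 exceeded the mean of length-matched lists (0.07) by 1.47, with 0.68 as the highest of them. The matched genes were drawn independently, so their range leaves out correlation between members, estimated at 0.2 for this list. No biological explanation was tested. Reads shared between Cyp2b, Cyp3a and Cyp4a paralogs stay open, and the adjusted p was 0.35 with an estimated correlation.

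Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real one, the real one itself, with 1378, and the highest of the others gave 0. Every other split put libraries of both groups together, so any difference between the groups widened the spread within its sides. The 0 calls of these splits therefore do not measure what chance gives. With 10 splits a share under 0.05 cannot be reached.

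Gene families with a common symbol stem and at least 8 tested members were compared with all other genes, 215 in all. Camera's adjusted p was under 0.05 for 44, 32 higher and 12 lower, of which 31 passed after the length correction and 0 with an estimated correlation (smallest adjusted p 0.66). Of the mitochondrial ribosomal protein genes, 12 of 48 Mrpl genes (median 0.48, adjusted p 1.9e-11) and 9 of 29 Mrps genes (median 0.45, 7.1e-07) were higher in XCKO and 0 lower. The peroxisome biogenesis family Pex (7 of 16 higher, median 0.47, 4.9e-06), the mitochondrial import family Timm (5 of 13, 0.63, 3.4e-05) and the ER membrane complex family Emc (5 of 9, 0.60, 4e-04) also had 0 lower members. These 5 families passed after the length correction, with 12 (Mrpl), 6 (Mrps), 7 (Pex), 3 (Timm) and 4 (Emc) higher members. Under total-count scaling their medians were 0.21 (Mrpl), 0.17 (Mrps), 0.21 (Pex), 0.36 (Timm) and 0.33 (Emc). The hepatocyte marker mean differed by 0.52 (XCKO minus XCON) beside them. The Toll-like receptor family Tlr (6 of 12 lower, median −1.43, 0.0023), the kinesin family Kif (5 of 33 lower, −0.78, 3e-04) and the interferon-induced Ifi family (9 of 14 lower, −1.51, 2.8e-05) had 0 higher members, and 4, 3 and 8 lower ones after the length correction. The macrophage and lymphocyte marker means differed by −1.16 and −1.09 (XCKO minus XCON) beside the Tlr and Ifi families. The cytosolic ribosomal protein families had 2 higher and 1 lower of 32 Rps genes and 4 higher and 1 lower of 46 Rpl genes. They passed as families before the length correction (Rps median 0.43, 0.00059, and Rpl median 0.31, 0.0019) and not after it (0.07 and 0.17). Their medians were 0.15 and 0.03 under total-count scaling, and many of these genes have pseudogenes that may share reads.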
